A study of Mus musculus with 8 samples.

How the data were processed

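Bulk RNA sequencing was carried out on CD8 T cells sorted from B16-OVA tumours, a mouse melanoma line that expresses the ovalbumin antigen. Tumour cells were placed under the skin of Rag2-deficient mice, which make no T or B cells of their own, 10 days before CD8 T cells were transferred into them. Per the labels, the transferred cells came from WT mice or from mice with floxed Nr4a1 and Nr4a2 alleles, a Cd8-driven Cre recombinase and the OT-I transgene, a T cell receptor that recognises ovalbumin. The labels do not say whether the WT cells also carried OT-I. Infiltrating CD3e+CD8+ cells were taken 10 days after transfer and sorted as PD1+Tim3- or PD1+Tim3+, and per the labels' protocols the cells of each implanted mouse formed a sample. RNA was extracted with a Qiagen column kit. Groups were taken from the labels, which give 2 libraries for each of the 4 combinations of genotype and population, 8 libraries in all. The columns of the PD1+Tim3- libraries name PD1 alone, and were assigned to that population because the Tim3+ columns are named separately.

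The deposited file is 1 table of whole-number counts per gene symbol, which the authors made for all 8 libraries. The submitters' processing notes name genome build mm10, cutadapt 1.18 and Bowtie2 2.2.5, without the role or order of each. The counting tool, the gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Bowtie2 does not split a read over an exon junction, so if it made the alignments to the genome, reads that cross a junction would be missing from the counts. A last line without a gene name equals the total of the genes in each column, and was left out of library sizes and tests. Without it the table holds 24976 genes. Genes that overlap others on either strand, such as Cxcl10 with Art3, are uncertain because the strand setting is not known. The same holds for near-identical genes, among them Ifitm1 and Ifitm2, the Bcl2a1 genes, the alpha and beta globin genes and Y-linked genes with X-linked relatives.

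Total counts ran from 1944999 in replicate 2 of the libraries labelled dKO PD1+Tim3- to 13418762 in replicate 2 of WT PD1+Tim3+. The 2 libraries of a group differed by more than sampling noise in all 4 groups, with a chi-square per gene of 3.16 to 17.5, so none was counted as a duplicate. Their log2 levels correlated across genes at Pearson r 0.974 to 0.990, where genes are not independent replicates.

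Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. Libraries were scaled by TMM factors, and genes were kept by the default low-count filter over the 4 groups, which left 13073 genes. The 8 libraries entered 1 fit with 4 group means and 4 residual degrees of freedom, so that the groups share their estimate of the spread. Fitted contrasts were the libraries labelled dKO against WT in each population, PD1+Tim3+ against PD1+Tim3- in each genotype, and the interaction, which is the difference between the 2 population contrasts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values of genes come from this test unless another tool is named. Errors of log2 fold changes are standard errors, obtained as the fold change over the square root of F. Group levels are means of CPM, counts scaled to the TMM-scaled size of each library, with the SD of 2 libraries. Marker levels of other cell types that carry an SD are on that scale too. Those given per library, as an average without an SD or as a highest value are CPM on unscaled totals over all genes. With 2 mice per group the p-values rest on the assumption that all groups vary alike.

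Gene lists were fixed before the data were examined. They are NR4A family, Stem-like and memory, Terminal exhaustion, Effector and cytotoxic, TCR-induced transcription factors and early genes, Tissue residency, Trafficking and chemokine receptors, Cell cycle, Type I interferon response, Glycolysis, Hypoxia, Mitochondrial respiratory chain, Cholesterol synthesis, Heat shock and stress, Apoptosis regulators, T cell identity, Ribosomal proteins and Mitochondrially encoded. Markers of other cells that a tumour sort could hold form the lists B16 melanoma cells, Macrophages and monocytes, Dendritic cells, Neutrophils, B cells, NK cells, CD4 and regulatory T cells, Fibroblasts and endothelium and Erythroid cells. The 25 lists with 3 or more tested genes were compared with all other genes by camera of limma 3.58.1 with a preset correlation of 0.01, and p-values were adjusted over the lists of a contrast. Camera was repeated with the correlation estimated from the data, a setting in which it takes its p from the 4 residual degrees of freedom. Fry tested whether the genes of a list moved, on balance, one way. Fry compares a list with no change, so ranges over the alternatives of a list hold p-values of camera alone. Neutrophils and B cells had fewer than 3 tested genes and were not tested. The table counts Cd244 and Cd244a separately, and the annotation used here places them at 1 gene, so the 23 tested members of Terminal exhaustion are 22 genes. Without Cd244 that list was called in the same contrasts.

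The genes named for each contrast were set by a rule written before the data were examined. It takes Nr4a1, Nr4a2, Nr4a3 and the sort markers Pdcd1, Havcr2, Cd8a and Cd3e, then the 10 called genes with the smallest p in each direction whose libraries do not overlap, without predicted genes, and then members of the lists as examples. For the interaction 5 genes per direction were taken whether or not they passed. Not every gene that the rule takes is described. The fit was tested on simulated counts with a mean per gene averaged over the groups, the library sizes of these data and 200 changed genes. It recovered 79.1% of genes changed by a fold of 2 for the genotype contrast in PD1+Tim3- cells, 89.6% for that in PD1+Tim3+ cells, 86.6% for the population contrast in WT, 68.7% for that in the libraries labelled dKO and 38.8% for the interaction. Genes without a change made up 5 of 153, 8 of 154, 17 of 167, 5 of 119 and 8 of 96 calls in that order. Counts were drawn gene by gene, without shifts shared across a library. The least abundant genes were left unchanged, so recovery in the real libraries may be lower.

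Alternatives fixed before the data were examined were RLE size factors of the DESeq2 type, upper-quartile factors, no low-count filter, a stricter filter, the Wald test of DESeq2 1.42.0, limma-voom, robust empirical Bayes, the replicate number as a block, a fit of only the 4 libraries compared, an adjusted p under 0.10, and each library left out in turn. Alternatives chosen after seeing the data were offsets that remove the trend of each library with transcript length, a fit without ribosomal RNA, mitochondrial genes and 5 very abundant genes, a fit without replicate 2 of both groups labelled dKO, and a block with crossed numbers. Positions and transcript lengths come from the GENCODE M21 annotation of GRCm38, which is the mm10 assembly, and a length was found for 93.4% of the tested genes.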

Results

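RNA from CD8 T cells that had entered B16-OVA melanomas was sequenced in bulk in 8 libraries, 2 for each combination of donor genotype and sorted population. The donors were WT or, by their label, lacked Nr4a1 and Nr4a2 in CD8 T cells, and are called dKO here. The labels give the dKO donors a Cd8-driven Cre and the OT-I receptor, and do not say whether WT donors carried OT-I. Receptor specificity may therefore be mixed with the genotype label in both genotype contrasts. NR4A factors are nuclear receptors that T cell receptor signals induce and that limit T cell function in tumours. Cells were sorted as PD1+Tim3-, a gate that holds the less differentiated exhausted cells, or PD1+Tim3+, which holds terminally exhausted cells, where PD1 and Tim3 are inhibitory receptors encoded by Pdcd1 and Havcr2. The study asks how loss of both factors alters these cells, in particular the stem-like pool marked by TCF1, the product of Tcf7. Total counts of the 2 libraries were 7828156 and 4801738 in WT PD1+Tim3-, 5519221 and 1944999 in PD1+Tim3- cells labelled dKO, 5489394 and 13418762 in WT PD1+Tim3+, and 5256474 and 5609692 in PD1+Tim3+ cells labelled dKO. The ribosomal RNA genes Rn45s and Rn18s took 2.36% ± 0.00432 and 1.80% ± 0.277 of counts in WT and labelled dKO PD1+Tim3- cells (mean and SD, n = 2), and 6.99% ± 0.660 and 8.12% ± 0.336 in PD1+Tim3+ cells. In a principal component analysis the first component held 45.7% of the variance and separated the populations. Component 2 held 19.1% and set apart replicate 2 of PD1+Tim3- labelled dKO, the library with the lowest total.

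The targeted genes were counted in every library, and neither passed as lower in the libraries labelled dKO. Nr4a1, which encodes the receptor NUR77, stood at 979 and 824 CPM in the 2 WT PD1+Tim3- libraries and at 1331 and 1489 in those labelled dKO, a log2 fold change of 0.64 ± 0.13 (SE) with an adjusted p of 0.126. In PD1+Tim3+ cells it stood at 803 and 789 CPM in WT and 1194 and 1175 in the libraries labelled dKO, 0.57 ± 0.13, adjusted p 0.0944. Adjusted over the 3 genes of the NR4A family list alone, the p of Nr4a1 was 0.00109 in PD1+Tim3- cells and 0.00261 in PD1+Tim3+ cells. Robust empirical Bayes and a fit without the low-count filter called it in both populations, and limma-voom in PD1+Tim3+ cells. Nr4a2, which encodes NURR1, stood at 933 ± 5.97 against 974 ± 23.0 CPM in PD1+Tim3- cells (labelled dKO against WT, mean and SD, n = 2) and 969 ± 21.8 against 1007 ± 38.6 CPM in PD1+Tim3+ cells. Its log2 fold changes were -0.06 ± 0.11, adjusted p 0.914, and -0.05 ± 0.11, adjusted p 0.921. Nr4a3, the family member that was not targeted, did not pass either, at 0.18 ± 0.11, adjusted p 0.718, and 0.10 ± 0.11, adjusted p 0.814. Nr4a1 lies on chromosome 15 from 101254269 to 101274795 on the forward strand, Nr4a2 on chromosome 2 from 57106830 to 57124003 on the reverse strand, and Nr4a3 on chromosome 4 from 48045153 to 48086447 on the forward strand, in GRCm38. The levels of Nr4a1 go against the label, and which exons are floxed is not given in the sources used here, so counts per gene may include parts that are not deleted. All genotype directions below are therefore those of the labels.

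**Figure D1:**
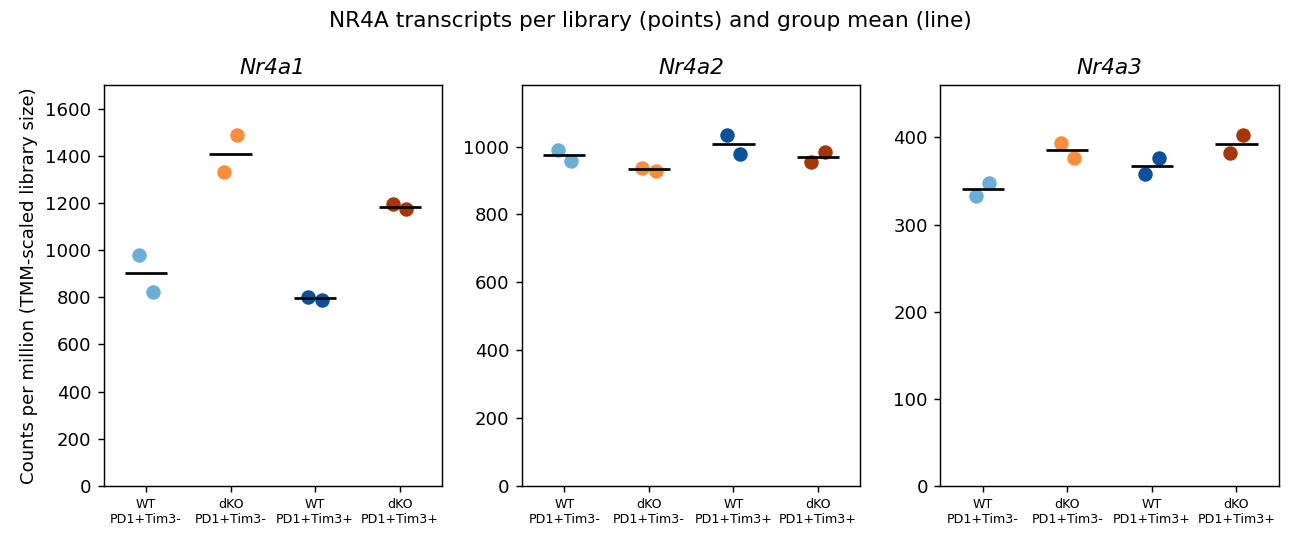
Levels of Nr4a1, Nr4a2 and Nr4a3 in each library, as CPM on TMM-scaled library sizes. Points are the 2 libraries of a group and lines are group means.

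In PD1+Tim3- cells the libraries labelled dKO had more Cxcl10, which encodes a chemokine that draws T cells bearing CXCR3, and more Id3, a regulator of memory and stem-like CD8 T cells. Cxcl10 stood at 77.2 ± 2.35 against 32.2 ± 1.78 CPM (labelled dKO against WT, mean and SD, n = 2), a log2 fold change of 1.27 ± 0.16 (SE). Id3 stood at 47.8 ± 3.03 against 23.8 ± 0.179 CPM, 1.02 ± 0.13, and both had an adjusted p of 0.0201. Gdpd3, which encodes a lipid-cleaving enzyme, fell to 11.2 ± 1.78 against 36.3 ± 5.27 CPM, -1.62 ± 0.18, with an adjusted p of 0.0201. The secreted protease inhibitor gene Serpine2 fell (-2.08 ± 0.26), as did Setbp1 (-2.12 ± 0.27), which encodes a DNA-binding protein, both at an adjusted p of 0.0201. Ubash3b, whose product is a phosphatase that dampens T cell receptor signals, fell to 34.5 ± 0.574 against 60.9 ± 0.528 CPM, -0.81 ± 0.11, adjusted p 0.0267. Tcf7, the gene of TCF1, stood at 318 ± 14.5 against 357 ± 21.6 CPM and did not pass, -0.16 ± 0.11, adjusted p 0.745, nor did Tox, a driver of exhaustion, at -0.21 ± 0.15, adjusted p 0.752. Of 13073 genes tested 6 passed, 2 higher and 4 lower, 5 of them by more than 2-fold, with 1081 at an unadjusted p under 0.05. DESeq2 called 6, of which 4 were shared, and limma-voom 0. The count was 0 without replicate 2 of WT PD1+Tim3-, without either PD1+Tim3- library labelled dKO or without either WT PD1+Tim3+ library, 1 without replicate 1 of WT PD1+Tim3-, and 27 without either PD1+Tim3+ library labelled dKO. Other settings gave 232 without the low-count filter, 56 with robust empirical Bayes and 1 without replicate 2 of both groups labelled dKO.

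TCR-induced transcription factors and early genes, which antigen signals switch on within hours, rose as a group in the PD1+Tim3- libraries labelled dKO. Of 24 members 23 had a positive fold change, with a median log2 of 0.25 (camera adjusted p 1.67e-09, adjusted p = 0.223 with an estimated correlation). Among them were the phosphatase gene Dusp2 at 0.60 ± 0.14, the activation factors Irf4 at 0.59 ± 0.10 and Jun at 0.56 ± 0.10, and Egr2 at 0.50 ± 0.13, while Spry2, an inhibitor of receptor signalling, stood at -0.66 ± 0.21. Adjusted over the list alone 9 rose and 1 fell, and over all genes edgeR, DESeq2 and limma-voom each called 0, with 13 at an unadjusted p under 0.05. Effector and cytotoxic genes fell as a group, with a median of -0.29 over 21 members (camera adjusted p 0.0177, adjusted p = 0.341 with an estimated correlation). Adjusted over that list alone 6 fell, among them Zeb2 at -1.01 ± 0.20, the granzyme gene Gzmb at -0.49 ± 0.13 and the perforin gene Prf1 at -0.48 ± 0.14. In the other direction 2 rose, Tnf at 0.83 ± 0.13 and Tbx21 at 0.51 ± 0.10. Of 20 stem-like and memory genes 1 rose, Id3, and 19 did not pass, with a median of -0.19 that did not pass by camera (adjusted p 0.0587). Adjusted over the list alone Id3 and Ltb rose, and Ccr7, Myb and Dapl1 fell, at -0.61 ± 0.11, -0.58 ± 0.10 and -0.79 ± 0.26. The 23 terminal exhaustion genes did not pass as a group (median -0.11, adjusted p 0.141), with 3 lower over the list alone, Cd38 at -0.87 ± 0.25, Tnfrsf9 at -0.41 ± 0.12 and Ikzf2 at -0.44 ± 0.11.

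Cell cycle genes rose in the PD1+Tim3- libraries labelled dKO, with 25 of 28 positive and a median of 0.22 (camera adjusted p 1.95e-04, adjusted p = 0.383 with an estimated correlation). Examples are the thymidine kinase gene Tk1 at 0.74 ± 0.23 and Mcm6, of the replicative helicase, at 0.42 ± 0.12. The cell cycle median ran from 0.11 to 0.43 with a library left out. Type I interferon response genes rose with 19 of 23 positive and a median of 0.16 (0.00505, adjusted p = 0.341 with an estimated correlation), among them the RNA sensor gene Ifih1 at 0.55 ± 0.16. Glycolysis genes rose with 12 of 14 positive, a median of 0.17 (0.00803, adjusted p = 0.435 with an estimated correlation) and the glucose transporter gene Slc2a1 at 0.35 ± 0.14. Apoptosis regulators rose with 10 of 12 positive, a median of 0.20 (0.00503, adjusted p = 0.341 with an estimated correlation) and the survival gene Bcl2l1 at 0.41 ± 0.14. Heat shock and stress genes rose with a median of 0.17 over 12 members (0.0294, adjusted p = 0.341 with an estimated correlation), 3 of them over the list alone, Hspa1a, Gadd45b and Ddit3. Their median ran from 0.03 to 0.20 with a library left out. Ribosomal protein genes fell, with 86 of 103 negative and a median of -0.37 (1.16e-10, adjusted p = 0.341 with an estimated correlation). The ribosomal median ran from -0.50 to -0.24 with a library left out. Counts in transcripts under 1000 bases made up 23.0% ± 1.08 in the libraries labelled dKO and 24.7% ± 0.572 in WT (SD, n = 2). Ribosomal protein genes took 12.6% ± 1.02 and 13.6% ± 0.933 of counts, and those under 1000 bases are part of that share. In these 6 lists and the effector list edgeR, DESeq2 and limma-voom called 0 members over all genes, with 5, 6, 2, 4, 5, 24 and 11 at an unadjusted p under 0.05 in the order given. Of the lists that camera did not call, tissue residency had an adjusted p of 0.116, with 4 higher and 1 lower over the list alone, and trafficking 0.922. NK cell genes leaned downward at 0.0587 (fry adjusted p 0.0189), with Fcer1g and Eomes lower over the list alone. NR4A family and T cell identity genes both stood at 0.0587, with Nr4a1 the 1 member of its list that was higher over the list alone. With offsets for transcript length both lists passed, at 0.0406 in a range up to 0.341 and at 0.0152 in a range up to 0.562 over their alternatives.

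In PD1+Tim3+ cells the libraries labelled dKO had less Ccr7, which encodes a chemokine receptor that guides naive and memory T cells into lymph nodes, and more of the antiviral genes Ifitm1 and Ifitm2. Ccr7 fell to 46.6 ± 3.14 against 122 ± 2.73 CPM (labelled dKO against WT, mean and SD, n = 2), a log2 fold change of -1.39 ± 0.11 (SE) with an adjusted p of 2.85e-04. Ifitm1 rose to 77.3 ± 8.50 against 23.1 ± 2.13 CPM, 1.75 ± 0.13, adjusted p 2.85e-04. Ifitm2, whose sequence is close to that of Ifitm1, rose to 22.9 ± 0.517 against 5.84 ± 0.324 CPM, 1.95 ± 0.17, adjusted p 5.93e-04. The transcription factor genes Myb, Irf8 and Setbp1 fell, Myb to 44.9 ± 2.38 against 87.0 ± 0.606 CPM, -0.95 ± 0.11, adjusted p 0.00239. The values of Irf8 and Setbp1 were -0.94 ± 0.10, adjusted p 0.00239, and -1.54 ± 0.21, adjusted p 0.00943. Serpine2 fell (-1.32 ± 0.13, adjusted p 0.00108), the chemokine receptor gene Cxcr4 (-0.96 ± 0.12, adjusted p 0.00791), and Samd3 (-0.83 ± 0.11, adjusted p 0.00791). The membrane protein genes that fell were Nsg2 (-0.96 ± 0.13, adjusted p 0.0113), and Itm2a (-0.78 ± 0.11, adjusted p 0.0131). Cd40lg, which encodes the helper ligand CD154, rose to 13.4 ± 0.597 against 4.81 ± 0.0671 CPM, 1.47 ± 0.20, adjusted p 0.00943. The lectin gene Lgals1 rose to 585 ± 97.2 against 286 ± 14.6 CPM, 1.04 ± 0.14, adjusted p 0.0106. The lipid receptor gene Gpr55 rose (1.76 ± 0.18, adjusted p 0.00109), the early-response repressor Klf10 (0.75 ± 0.11, adjusted p 0.0131), and the cell cycle gene Cks2 (0.75 ± 0.11, adjusted p 0.0131). Transcripts of Ifitm1, Ifitm2, Lgals1 and Cks2 are under 1000 bases. Genes of 500 to 700 bases had a median log2 fold change of 0.31 in this contrast, and those of 700 to 1000 bases 0.11. With offsets for transcript length all calls of named genes were kept. Of the 10 leading higher genes 3 lie on the Y chromosome, Ddx3y at 1.57 ± 0.13, adjusted p 2.85e-04, Eif2s3y at 1.27 ± 0.11, adjusted p 5.69e-04, and Kdm5d at 1.19 ± 0.17, adjusted p 0.0131. Havcr2 itself stood at 0.42 ± 0.12, adjusted p 0.166, Tcf7 at -0.23 ± 0.11, adjusted p 0.440, and Tox at -0.38 ± 0.15, adjusted p 0.326, and none of these passed.

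Of 13073 genes 82 passed in PD1+Tim3+ cells, 34 higher and 48 lower in the libraries labelled dKO, 32 of them by more than 2-fold. DESeq2 called 71 and limma-voom 74, and 1570 had an unadjusted p under 0.05. Left-out libraries moved the count to 10 without replicate 1 and 6 without replicate 2 of WT PD1+Tim3+, and to 41 and 39 without replicate 1 and 2 of PD1+Tim3- labelled dKO. It moved to 405, with 334 higher and 71 lower, and to 46 without replicate 1 and 2 of PD1+Tim3+ labelled dKO. Among those left at 6 were Ifitm1, Ifitm2, Ddx3y, Eif2s3y and Ccr7. In other settings the count was 486 without the low-count filter, 325 higher and 161 lower, 39 in a fit of the 4 libraries compared and 15 without replicate 2 of both groups labelled dKO.

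**Figure D2:**
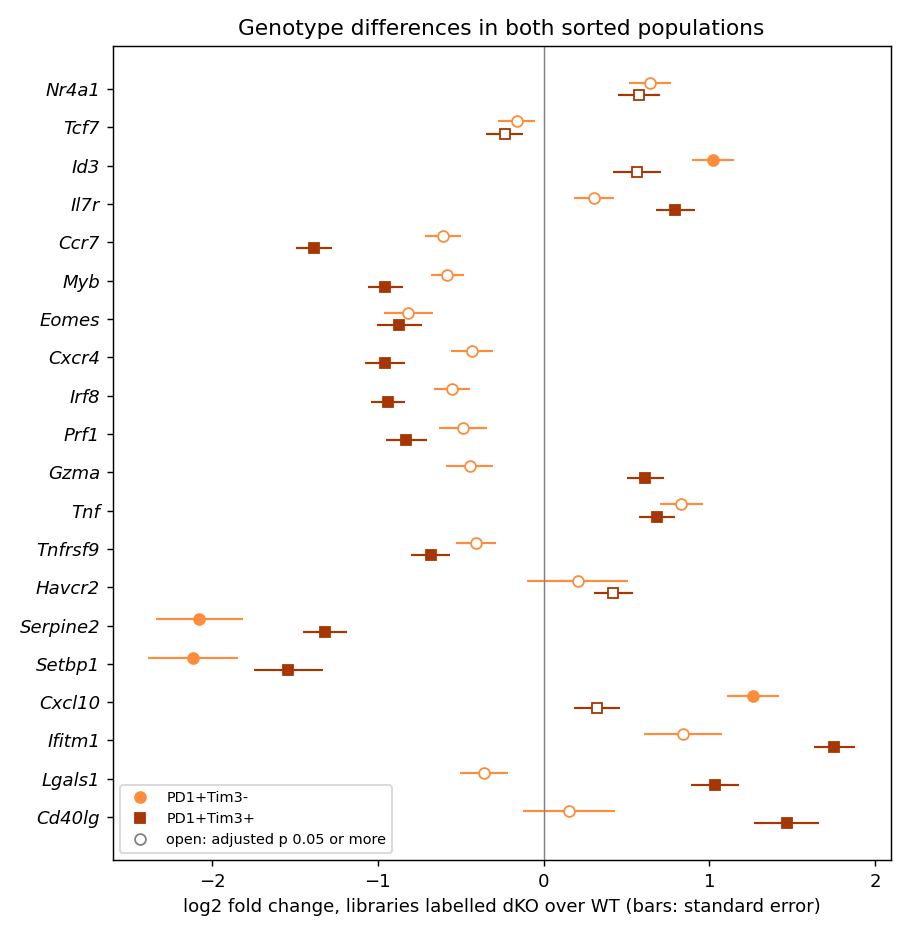
Log2 fold changes of 20 genes in the libraries labelled dKO against WT, in PD1+Tim3- and PD1+Tim3+ cells. Bars are standard errors and filled points have an adjusted p under 0.05.

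Stem-like and memory genes fell as a group in the PD1+Tim3+ libraries labelled dKO, with a median of -0.21 over 20 members (camera adjusted p 1.42e-05, adjusted p = 0.160 with an estimated correlation). Of these 3 fell, among them Ccr7 and Myb, 1 rose, the survival receptor gene Il7r at 0.80 ± 0.12, adjusted p 0.0136, and 16 did not pass. Adjusted over the list alone 6 fell, among them the follicle-homing receptor gene Cxcr5 at -1.55 ± 0.34 and Bach2, a repressor that guards memory, at -0.30 ± 0.11, and 3 rose, Il7r, S1pr1 and Id3 at 0.56 ± 0.14. Terminal exhaustion genes fell with a median of -0.27 over 23 members (0.0231, adjusted p = 0.294 with an estimated correlation). Only Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, fell over all genes, -0.68 ± 0.12, adjusted p 0.0303, and 22 did not pass. Over the list alone 5 fell, among them the inhibitory receptor genes Lag3 at -0.37 ± 0.12 and Tigit at -0.44 ± 0.13, and 4 rose, among them Havcr2 at 0.42 ± 0.12 and Maf at 0.72 ± 0.19. Of 21 effector and cytotoxic genes 2 rose, Tnf at 0.69 ± 0.11, adjusted p 0.0208, and the granzyme gene Gzma at 0.61 ± 0.11, adjusted p 0.0357, while Prf1 fell (-0.83 ± 0.12, adjusted p 0.0131), and 18 did not pass. As a group effector genes did not pass (adjusted p 0.637, median -0.07, mean 0.01), with 3 higher and 2 lower over the list alone. TCR-induced genes did not pass as a group here (median 0.13, camera adjusted p 0.0702), with 4 higher and 1 lower over the list alone. Over all genes edgeR, DESeq2 and limma-voom each called 0 of them, against 11 at an unadjusted p under 0.05. With offsets for transcript length the TCR-induced list passed upward (adjusted p 9.09e-04, in a range up to 0.400 over its alternatives).

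Cell cycle genes rose in PD1+Tim3+ libraries labelled dKO, with 26 of 28 positive and a median of 0.32 (camera adjusted p 2.63e-07, adjusted p = 0.294 with an estimated correlation). Over the list alone 3 rose, Mki67 at 0.51 ± 0.13, Ccna2 at 0.71 ± 0.16 and Birc5 at 0.59 ± 0.17. Ribosomal protein genes rose with 93 of 103 positive and a median of 0.42 (2.78e-14, adjusted p = 0.294 with an estimated correlation), beside 22.8% ± 1.24 of counts in transcripts under 1000 bases against 20.6% ± 0.265 in WT (SD, n = 2). They took 11.3% ± 0.963 against 9.94% ± 0.0365 of counts themselves, and those under 1000 bases are part of that share. The 2 libraries labelled dKO stood apart, with ribosomal medians of -0.30 and 0.23 relative to the mean of the 8 libraries against -0.46 in both of WT. The difference was 0.15 without replicate 2 and 0.70 without replicate 1. Glycolysis genes fell with 13 of 14 negative and a median of -0.24 (0.00445, adjusted p = 0.400 with an estimated correlation), for example Pkm, of pyruvate kinase, at -0.39 ± 0.13 and Pfkl, of phosphofructokinase, at -0.39 ± 0.12. Mitochondrial respiratory chain genes rose with a median of 0.13 over 27 members (0.0231, adjusted p = 0.294 with an estimated correlation), 7 of them over the list alone, among them Cox6c at 0.80 ± 0.22 and Ndufa4 at 0.69 ± 0.20. The median of the respiratory chain list ran from 0.05 to 0.19 with a library left out. With offsets for transcript length that list had an adjusted p of 0.454, the highest of a range from 0.0351 over its alternatives. Heat shock and stress genes rose with a median of 0.20 (0.0231, adjusted p = 0.294 with an estimated correlation), 2 of 12 over all genes, Gadd45b at 0.73 ± 0.11, adjusted p 0.0169, and Atf3 at 0.91 ± 0.17, adjusted p 0.0458. Of 23 type I interferon response genes 1 rose, Isg15 at 0.70 ± 0.13, adjusted p 0.0360, and the group did not pass (0.879). Over all genes edgeR called 0 members of the cell cycle, glycolysis, respiratory chain and ribosomal protein lists, DESeq2 0, 0, 0 and 3, and limma-voom 0 in each, with 10, 5, 9 and 51 at an unadjusted p under 0.05.

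Markers of other cells moved with the label in PD1+Tim3+ cells too. Erythroid genes rose as a group with a median of 1.95 over 5 members (camera adjusted p 4.18e-04, adjusted p = 0.294 with an estimated correlation), 4 of them over the list alone. The erythroid median ran from 0.56 to 3.43 with a library left out. The beta globin gene Hbb-bs stood at 37.3 and 8.38 CPM in the 2 libraries labelled dKO and at 13.1 and 2.16 in WT. No erythroid gene passed in edgeR over all genes, a count of 0 with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom. NK cell genes fell with a median of -0.41 over 6 members (0.0380, adjusted p = 0.294 with an estimated correlation), where the 1 that fell was Eomes at -0.87 ± 0.14, adjusted p 0.0183, a factor that CD8 T cells also make. The NK cell median ran from -0.50 to -0.15 with a library left out. With length offsets the NK cell list had 0.206, in a range of 0.106 to 0.294 over its alternatives. CD4 and regulatory T cell genes rose with a median of 0.13 over 4 members (0.0380, adjusted p = 0.400 with an estimated correlation), where the 1 that rose was Cd40lg, and had 0.147 with length offsets, in a range of 0.0496 to 0.400. Their median ran from 0.02 to 0.24 with a library left out. After the values were seen, Uty and Xist were added as markers of donor sex. Uty, on the Y chromosome, stood at 1.29 ± 0.20, adjusted p 0.0208, and Xist, which females express, at -0.44 ± 0.11, adjusted p 0.147, in PD1+Tim3+ cells. The 4 Y-linked genes pooled gave 1.35 ± 0.07 in PD1+Tim3+ cells, where all 4 passed, and 0.74 ± 0.08 in PD1+Tim3- cells, where edgeR called 0. These errors take the 4 genes as independent, though they were counted in the same libraries. Tissue residency (adjusted p 0.0983), trafficking (0.637) and NR4A family genes (0.246) did not pass, with 1 of 12 trafficking genes lower, Cxcr4.

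The genotype calls of the 2 populations, which share no library, overlapped in 3 genes that fell in both, Serpine2, Setbp1 and Gdpd3. Independent lists of this size would share 0.0147 lower genes by chance (Fisher exact p 1.85e-07). In the higher direction they shared 0 in edgeR, against 0.00520 by chance. Both contrasts come from 1 fit with a shared spread, and the populations may come from the same mice. The chance values and the Fisher p assume an independence that is not shown. Of the 48 lower and 34 higher genes of PD1+Tim3+ cells, 85.4% and 79.4% had the same sign in PD1+Tim3- cells. Id3 passed in PD1+Tim3- cells at 1.02 ± 0.13 and not in PD1+Tim3+ cells at 0.56 ± 0.14, with an interaction of -0.46 ± 0.19, adjusted p 0.452. Ccr7 passed in PD1+Tim3+ cells at -1.39 ± 0.11 and not in PD1+Tim3- cells at -0.61 ± 0.11, with an interaction of -0.78 ± 0.15, adjusted p 0.200. At an unadjusted p under 0.01 the populations shared 39 higher genes against 3.93 by chance, 47 lower against 1.98, and 13 moved in opposite directions. At that threshold 39.8% of the 362 higher and 72.2% of the 205 lower genes of PD1+Tim3+ cells had the same sign in PD1+Tim3- cells.

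Between the sorted populations of WT cells, PD1+Tim3+ cells had far more of the cytotoxic genes and less of the genes of stem-like cells than PD1+Tim3- cells. Havcr2, which encodes the sort marker Tim3, rose to 42.7 ± 1.27 against 2.92 ± 0.901 CPM (mean and SD, n = 2), a log2 fold change of 3.82 ± 0.18 (SE) with an adjusted p of 2.69e-06. The granzyme genes Gzmb, Gzma and Gzmk rose, Gzmb to 948 ± 91.4 against 212 ± 11.1 CPM, 2.16 ± 0.13, adjusted p 1.29e-05. Gzma had 1.79 ± 0.12, adjusted p 1.80e-05, and Gzmk 2.94 ± 0.20, adjusted p 1.80e-05. The death ligand gene Fasl rose to 83.6 ± 0.570 against 24.7 ± 3.17 CPM, 1.77 ± 0.11, adjusted p 1.31e-05. Ccr2, a receptor for inflammatory chemokines, rose to 163 ± 8.67 against 43.3 ± 5.33 CPM, 1.92 ± 0.12, adjusted p 1.29e-05. The lectin gene Lgals3 rose to 164 ± 18.1 against 24.6 ± 3.37 CPM, 2.74 ± 0.18, adjusted p 1.31e-05. Serpine2 rose (2.32 ± 0.14, adjusted p 1.29e-05), the protease gene Adam8 (2.73 ± 0.18, adjusted p 1.31e-05), and the immunosuppressive ligand gene Fgl2 (2.15 ± 0.15, adjusted p 1.80e-05). Myb, a factor that stem-like CD8 T cells need, fell to 87.0 ± 0.606 against 216 ± 8.69 CPM, -1.31 ± 0.10, adjusted p 3.59e-05. The cytokine receptor gene Il6st fell (-1.16 ± 0.11, adjusted p 1.53e-04), Nsg2 (-1.13 ± 0.11, adjusted p 2.76e-04), Actn1 (-1.35 ± 0.16, adjusted p 6.10e-04), and the lipid enzyme gene Elovl6 (-1.07 ± 0.14, adjusted p 0.00133). Pdcd1 did not pass, -0.18 ± 0.17, adjusted p 0.482, nor did Cd3e at 0.33 ± 0.12, adjusted p 0.0914, or Nr4a1 at -0.18 ± 0.13, adjusted p 0.366. Cd8a rose (0.41 ± 0.12, adjusted p 0.0389), a call that was lost in several settings, among them DESeq2 and each fit without a PD1+Tim3- library or a WT PD1+Tim3+ library.

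The WT contrast passed in 2223 genes, 1078 higher and 1145 lower in PD1+Tim3+ cells, 888 of them by more than 2-fold. Less studied genes that fell were Lrriq1 (-1.75 ± 0.20, adjusted p 6.53e-04), Fam241a (-0.91 ± 0.11, adjusted p 8.03e-04), Grid2ip (-1.67 ± 0.20, adjusted p 8.75e-04), and Tmem247 (-1.72 ± 0.22, adjusted p 0.00125). DESeq2 called 1303 genes, and the count was 529 without replicate 1 of WT PD1+Tim3- and 426 and 563 without replicate 1 and 2 of WT PD1+Tim3+.

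Effector and cytotoxic genes rose as a group in WT PD1+Tim3+ cells, 19 of 21 over all genes and 2 not passing, with a median of 1.01 (camera adjusted p 3.92e-30, adjusted p = 0.0296 with an estimated correlation). Among the 19 were the interferon gamma gene Ifng at 1.61 ± 0.11, the chemokine gene Ccl3 at 1.40 ± 0.11, Klrg1 at 2.63 ± 0.34 and Prf1 at 0.80 ± 0.12. Of 23 terminal exhaustion genes 13 rose, 2 fell and 8 did not pass, with a median of 0.66 (1.98e-10, adjusted p = 0.0384 with an estimated correlation). Besides Havcr2 those that rose included the ectoenzyme gene Entpd1 at 2.72 ± 0.21, Tigit at 0.87 ± 0.13, Lag3 at 0.38 ± 0.12 and Prdm1, the gene of the repressor Blimp-1, at 1.61 ± 0.25. Against these Tox fell (-0.65 ± 0.13) and Ikzf2 (-0.73 ± 0.11). Stem-like and memory genes fell, 12 of 20, with 1 higher and 7 not passing and a median of -0.43 (3.97e-07, adjusted p = 0.0384 with an estimated correlation). Tcf7 fell (-0.80 ± 0.11, adjusted p 0.00169), Id3 (-1.03 ± 0.13), Slamf6 (-0.50 ± 0.13), Il7r (-0.48 ± 0.12) and Cxcr5 (-1.08 ± 0.23). The 1 that rose was Ltb at 0.52 ± 0.12, and Ccr7 did not pass at -0.17 ± 0.10. Cell cycle genes rose, 22 of 28 with a median of 0.93 (9.69e-18, adjusted p = 0.137 with an estimated correlation), among them Mki67 at 1.23 ± 0.14 and Rrm2 at 1.72 ± 0.19. Of 12 trafficking and chemokine receptor genes 7 rose and 1 fell, with a median of 0.53 (3.51e-07, adjusted p = 0.109 with an estimated correlation), where Cxcr3 stood at 0.55 ± 0.11, the adhesion receptor gene Cd44 at 0.54 ± 0.11 and Klf3 at -0.59 ± 0.13. Tissue residency genes rose, 3 of 11 with 1 lower and a median of 0.78 (0.00344, adjusted p = 0.122 with an estimated correlation), with Itga1 at 1.66 ± 0.20, Cxcr6 at 1.59 ± 0.14 and Rgs10 at -0.51 ± 0.15.

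Glycolysis genes rose in WT PD1+Tim3+ cells, 9 of 14 with a median of 0.45 (camera adjusted p 1.79e-05, adjusted p = 0.196 with an estimated correlation), for example Aldoa at 0.88 ± 0.13 and the glucose transporter gene Slc2a3 at 0.75 ± 0.12. Of 24 TCR-induced genes 9 rose and 2 fell, with a median of 0.25 (0.0179, adjusted p = 0.196 with an estimated correlation), where Dusp2 stood at 0.81 ± 0.14, Nfkbiz at 0.73 ± 0.11 and Egr3 at -0.64 ± 0.11. Type I interferon response genes rose, 5 of 23 with 1 lower and a median of 0.26 (0.0367, adjusted p = 0.181 with an estimated correlation). Apoptosis regulators rose, 6 of 12 with a median of 0.46 (1.61e-04, adjusted p = 0.181 with an estimated correlation). The examples are Mx1 at 0.71 ± 0.15, Ifi27l2a at -1.15 ± 0.20, Bak1 at 0.77 ± 0.13 and Bcl2l1 at 0.68 ± 0.12. Ribosomal protein genes fell, 72 of 103 with 1 higher and a median of -0.88 (1.64e-23, adjusted p = 0.139 with an estimated correlation), beside 20.6% ± 0.265 of counts in transcripts under 1000 bases against 24.7% ± 0.572 in PD1+Tim3- cells (SD, n = 2). They took 9.94% ± 0.0365 against 13.6% ± 0.933 of counts themselves, and those under 1000 bases are part of that share. Mitochondrially encoded genes fell, 3 of 16 with a median of -0.30 (0.0179, adjusted p = 0.196 with an estimated correlation). Their median ran from -0.31 to -0.15 with a library left out. Of the markers of other cells, dendritic cell genes rose, 4 of 6 with a median of 1.88 (5.55e-05, adjusted p = 0.109 with an estimated correlation). So did CD4 and regulatory T cell genes, 3 of 4 with a median of 1.15 (7.76e-05, adjusted p = 0.137 with an estimated correlation), and NK cell genes, 2 of 6 with a median of 0.67 (0.0179, adjusted p = 0.139 with an estimated correlation). With length offsets the NK cell list had 0.0578, in a range of 0.0133 to 0.139 over its alternatives. The invariant chain gene Cd74 stood at 17.9 ± 2.09 against 5.89 ± 0.118 CPM in WT, 1.58 ± 0.21, and Rora at 110.4 ± 8.59 against 45.3 ± 3.44 CPM, 1.28 ± 0.11. The class II genes H2-Ab1 and H2-Aa stood at 2.76 ± 0.47 and 2.18 ± 0.38 and Foxp3 at 2.75 ± 0.61. Cd4 itself had too few counts to be tested and stood at 0 CPM in all PD1+Tim3+ libraries. Foxp3 stood at 2.73 and 2.38 CPM on unscaled totals in WT PD1+Tim3+, against 0.383 and 0.208 in WT PD1+Tim3-. Whether the transcripts of these lists came from the CD8 T cells or from other cells was not tested.

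Adjusted over each list alone the WT contrast gave 14 higher and 2 lower exhaustion genes, 19 and 0 effector, 1 and 12 stem-like, and 25 and 0 cell cycle genes. It gave 11 and 2 TCR-induced, 8 and 1 interferon, 10 and 0 glycolysis, 7 and 0 apoptosis and 3 and 78 ribosomal protein genes. Hypoxia genes did not pass as a group (adjusted p 0.0714) with 3 of 11 higher, among them Bnip3, a mitophagy gene, at 0.92 ± 0.21, and passed with length offsets (0.0365, in a range up to 0.196). T cell identity genes (0.182) had 2 of 10 higher, Cd8a and Thy1 at 0.45 ± 0.14, and cholesterol synthesis (0.434) had 1 of 16 higher, Sc5d at 0.48 ± 0.14. Heat shock and stress genes (0.972) had 2 of 12 higher, Hspa1a and Gadd45b, and 1 lower, the chaperonin gene Hspe1 at -0.71 ± 0.14. Respiratory chain genes (0.813) had 1 of 27 higher, Uqcrfs1, and 6 lower, among them Ndufa1 at -1.13 ± 0.29.

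Among the libraries labelled dKO, PD1+Tim3+ cells differed from PD1+Tim3- cells in much the same genes, led by Gzma and Havcr2. Gzma rose to 183 ± 18.0 against 25.7 ± 1.52 CPM (mean and SD, n = 2), a log2 fold change of 2.85 ± 0.14 (SE) with an adjusted p of 2.16e-06. Havcr2 rose to 57.4 ± 1.13 against 3.38 ± 0.333 CPM, 4.03 ± 0.19, adjusted p 2.16e-06. Gzmb rose to 789 ± 89.9 against 151 ± 0.837 CPM, 2.39 ± 0.14, adjusted p 5.68e-06, and Ccr2, Lgals3, Fasl and Adam8 rose, with 2.39 ± 0.13, 2.99 ± 0.19, 1.91 ± 0.13 and 2.81 ± 0.20. The antiviral gene Ifitm1 rose to 77.3 ± 8.50 against 8.62 ± 0.423 CPM, 3.18 ± 0.17, adjusted p 3.33e-06, and the ribosomal RNA genes Rn18s and Rn45s rose too, with 2.25 ± 0.15 and 2.10 ± 0.15. Myb fell to 44.9 ± 2.38 against 144 ± 1.57 CPM, -1.69 ± 0.11, adjusted p 1.21e-05. Id3 fell to 17.2 ± 0.956 against 47.8 ± 3.03 CPM, -1.48 ± 0.14, adjusted p 1.07e-04. The membrane protein genes Nsg2, Il6st and Itm2a fell, with -1.93 ± 0.14, -1.62 ± 0.12 and -1.46 ± 0.12, and Fam241a (-1.24 ± 0.12). Izumo1r, which encodes the folate receptor 4 of regulatory and antigen-experienced T cells, fell (-1.41 ± 0.15), the surface ADP-ribosyltransferase gene Art2b (-2.07 ± 0.23) and the antigen presentation gene H2-Ob (-3.53 ± 0.39). Tcf7 fell to 174 ± 3.39 against 318 ± 14.5 CPM, -0.87 ± 0.11, adjusted p 0.00123, and Tox (-0.81 ± 0.16, adjusted p 0.0124). Pdcd1 at -0.19 ± 0.18, adjusted p 0.594, Cd8a at 0.16 ± 0.12, adjusted p 0.481, and Nr4a1 at -0.25 ± 0.13, adjusted p 0.265, did not pass, where Cd8a had an interaction of -0.26 ± 0.17, adjusted p 0.682.

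In the libraries labelled dKO 1298 genes passed between the populations, 681 higher and 617 lower, 639 of them by more than 2-fold. The count was 119 and 288 without replicate 1 and 2 of PD1+Tim3- labelled dKO, 734 without replicate 1 of PD1+Tim3+ labelled dKO, 765 and 764 without replicate 1 and 2 of WT PD1+Tim3+, and 649 without replicate 2 of both groups labelled dKO.

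Of 21 effector and cytotoxic genes 16 rose in PD1+Tim3+ cells labelled dKO and 5 did not pass (camera adjusted p 4.19e-39, adjusted p = 0.0156 with an estimated correlation). Among them were Klrg1 at 2.62 ± 0.46, Gzmc at 3.11 ± 0.46 and Ifng at 1.52 ± 0.11. Stem-like and memory genes fell, 11 of 20 with 9 not passing and a median of -0.46 (8.04e-13, adjusted p = 0.0156 with an estimated correlation). Besides Myb, Id3 and Tcf7 these included Ccr7 at -0.95 ± 0.11, adjusted p 6.83e-04, Slamf6 at -0.85 ± 0.13, and Lef1, a partner of TCF1, at -0.65 ± 0.11. Terminal exhaustion genes rose, 10 of 23 with 2 lower and a median of 0.63 (2.77e-08, adjusted p = 0.128 with an estimated correlation), among them Entpd1 at 2.73 ± 0.27 and Tigit at 0.74 ± 0.14. Cell cycle genes rose, 20 of 28 with a median of 1.22 (8.39e-21, adjusted p = 0.128 with an estimated correlation), with Ccna2 at 2.21 ± 0.22 and Mki67 at 1.71 ± 0.15. Trafficking genes rose, 6 of 12 with 1 lower and a median of 0.50 (8.43e-07, adjusted p = 0.128 with an estimated correlation). Tissue residency genes rose, 3 of 11 with a median of 0.28 (0.00136, adjusted p = 0.128 with an estimated correlation) and apoptosis regulators 6 of 12 with a median of 0.44 (0.00619, adjusted p = 0.350 with an estimated correlation). Their members included Itga4 at 0.57 ± 0.12, Itga1 at 2.33 ± 0.23 and Bak1 at 0.66 ± 0.14. Over the lists alone these 7 groups had 19 and 0, 0 and 11, 14 and 3, 22 and 0, 7 and 1, 5 and 1, and 7 and 0 genes higher and lower in the order given.

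Ribosomal protein genes did not pass as a group in the libraries labelled dKO (median -0.07, adjusted p 0.0887), with 1 higher and 2 lower over all genes. Glycolysis genes did not pass either (median 0.12, 0.525), with 0 called by edgeR or DESeq2, 1 by limma-voom and 2 at an unadjusted p under 0.05. TCR-induced genes had 5 of 24 higher, among them Nfkbiz at 0.82 ± 0.12, and 4 lower, among them Myc at -0.79 ± 0.12 and Egr2 at -0.65 ± 0.13, and did not pass as a group (0.664). With offsets for transcript length the ribosomal list passed downward (adjusted p 1.79e-07, in a range up to 0.844 over its alternatives), as did mitochondrially encoded genes (0.0366 against 0.533 without offsets, in a range up to 0.837). Of the markers of other cells, erythroid genes rose, 4 of 5 with a median of 4.63 (3.49e-04, adjusted p = 0.249 with an estimated correlation), where DESeq2 called 3 and limma-voom 0. The CD4 and regulatory T cell genes rose, 3 of 4 with a median of 1.30 (6.98e-07, adjusted p = 0.128 with an estimated correlation), and dendritic cell genes, 2 of 6 with a median of 1.05 (0.00620, adjusted p = 0.237 with an estimated correlation). Hba-a1, an alpha globin gene, stood at 0.544 and 1.03 CPM in the PD1+Tim3- libraries and 26.1 and 8.73 in the PD1+Tim3+ libraries.

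**Figure D3:**
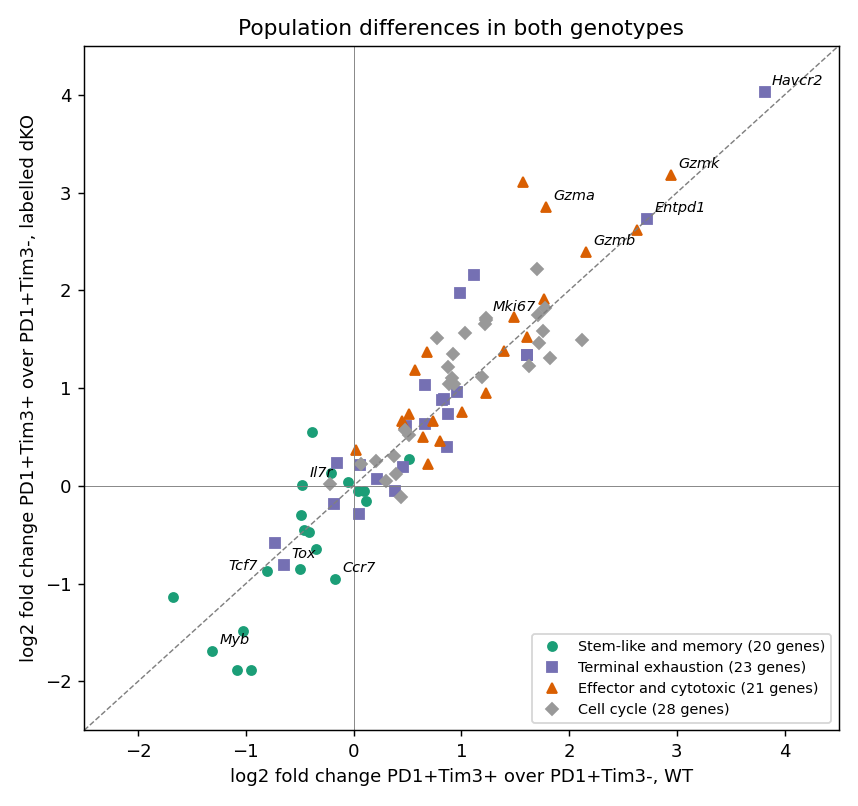
Log2 fold changes of PD1+Tim3+ against PD1+Tim3- cells in WT (horizontal) and in the libraries labelled dKO (vertical). Points are members of 4 gene lists, stem-like and memory (20), terminal exhaustion (23), effector and cytotoxic (21) and cell cycle (28).

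The population contrasts of the 2 genotypes, which share no library, had 428 higher genes in common, against 56.2 by chance, and 468 lower, against 54.0, while 7 called genes moved in opposite directions. Both contrasts come from the same fit, so the chance values assume an independence that is not shown. Of the genes called among the libraries labelled dKO, 93.1% of the higher and 96.3% of the lower had the same sign in WT. Havcr2, Gzmb, Gzma, Ccr2, Lgals3, Fasl and Adam8 were among the 10 leading higher genes of both, and Myb, Il6st, Nsg2 and Fam241a among the 10 leading lower ones.

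The interaction, which asks whether the population difference is not the same in the 2 genotypes, had Lgals1 and Itm2a among its leading genes, and neither passed. Lgals1 had an interaction of 1.39 ± 0.20 (SE, n = 2 per group), Higd1a, a mitochondrial hypoxia gene, 1.16 ± 0.20, Gzma 1.06 ± 0.18, S100a4, a calcium-binding protein gene, 1.79 ± 0.30, and Lcn4 1.84 ± 0.31. In the lower direction Itm2a had -0.83 ± 0.16, Ccr7 -0.78 ± 0.15, the cystine transporter gene Slc7a11 -1.21 ± 0.25 and Efcab1 -1.20 ± 0.26. Tcf7 had an interaction of -0.07 ± 0.16, adjusted p 0.913, and Nr4a1 of -0.07 ± 0.18, adjusted p 0.922. Over all genes edgeR called 0 and limma-voom 0, with a smallest adjusted p of 0.200 and 1320 genes at an unadjusted p under 0.05, while DESeq2 called 95. The count was 309 without replicate 1 of PD1+Tim3+ labelled dKO, 331 without the low-count filter and 4 with robust empirical Bayes. It was 223 with a block of crossed replicate numbers nested in genotype, with 216 genes higher. The 50 leading higher genes had a median transcript length of 693.5 bases. Of the 48 with a known length 81.2% were under 1000 bases, against 10.9% of all tested genes and none of the 47 leading lower ones. The median interaction was 0.67 over 239 genes of up to 500 bases and 0.52 over 358 genes of 500 to 700 bases. It was 0.10 over 737 genes of 700 to 1000 bases, and with offsets for transcript length the 3 medians were 0.05, 0.13 and -0.13.

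**Figure D4:**
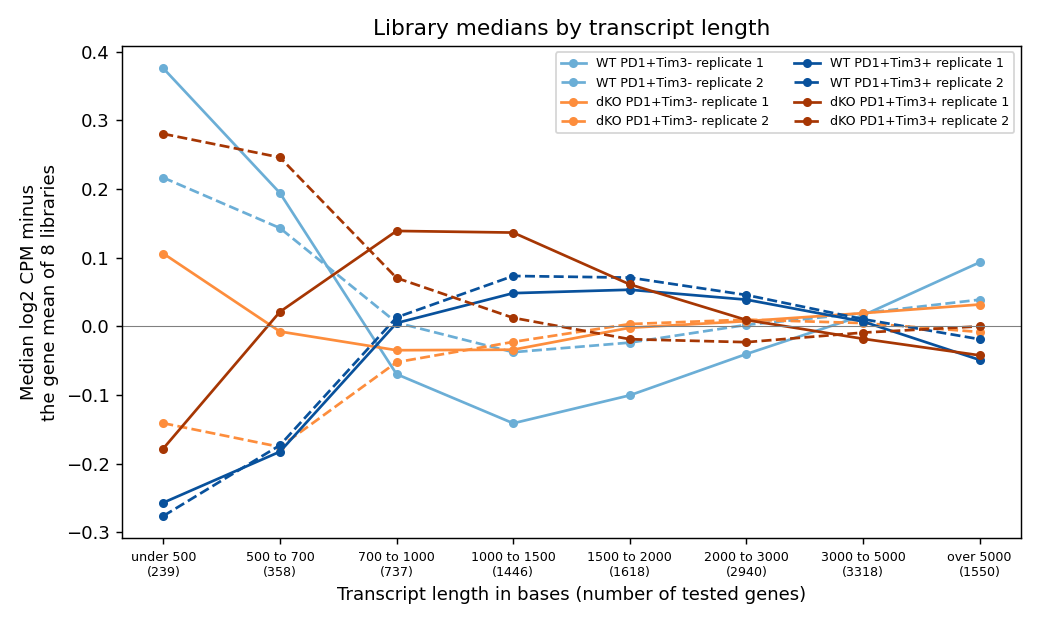
Median log2 level of genes relative to their mean over the 8 libraries, by length of the transcript. Each line is a library.

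Ribosomal protein genes had a median interaction of 0.79 over 103 members (camera adjusted p 4.12e-27, adjusted p = 0.440 with an estimated correlation). Their population difference was -0.88 in WT and -0.07 in the libraries labelled dKO, and 57 rose over the list alone, where edgeR and limma-voom called 0 over all genes, DESeq2 25 and 62 had an unadjusted p under 0.05. The -0.07 averages libraries that differ, and the interaction was 0.48 without replicate 2 and 1.07 without replicate 1 of PD1+Tim3+ labelled dKO. Glycolysis genes had a median of -0.41 over 14 (3.44e-05, adjusted p = 0.440 with an estimated correlation), between 0.45 in WT and 0.12 in the libraries labelled dKO. Examples were Pfkl at -0.65 ± 0.19 and Pkm at -0.60 ± 0.18, and 5 fell over the list alone. Respiratory chain genes had a median of 0.06 and a mean of 0.28 over 27 (0.0292, adjusted p = 0.440 with an estimated correlation), among them Ndufa4 at 1.36 ± 0.28, with 7 higher over the list alone. The median was -0.09 without replicate 1 of PD1+Tim3+ labelled dKO. With offsets for transcript length that list had an adjusted p of 0.883, in a range from 0.0386 over its alternatives. TCR-induced genes had a median of -0.16 (0.0461, adjusted p = 0.440 with an estimated correlation), between 0.25 in WT and 0.05 in the libraries labelled dKO, with Jun at -0.37 ± 0.15. Type I interferon response genes had a median of -0.24 (0.0461, adjusted p = 0.440 with an estimated correlation), between 0.26 and 0.08, with Oas3 at -0.50 ± 0.18, and erythroid genes 2.89 (0.00358, adjusted p = 0.440 with an estimated correlation). In these 5 lists edgeR and limma-voom called 0 genes and DESeq2 5 respiratory chain genes and 0 of the others, with 7, 8, 4, 6 and 2 at an unadjusted p under 0.05 in the order given. Fry called 0 of the 6 lists. Stem-like and memory genes did not pass (median -0.12, adjusted p 0.0689), with 2 lower over the list alone, among them Ccr7, and effector genes (0.253) had Gzma higher. With length offsets the stem-like list passed downward (adjusted p 0.0178, in a range up to 0.440 over its alternatives), and T cell identity genes, at 0.253 without them, had 0.0389 (range up to 0.909).

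Some lists had a median, a mean and a camera direction of different sign, and none of these passed. In the genotype contrast of PD1+Tim3- cells they were tissue residency (median -0.07, mean 0.18), respiratory chain (0.03 and -0.09, adjusted p 0.378) and B16 melanoma cell genes (0.12 and -0.49, 0.526). In that of PD1+Tim3+ cells they were effector genes, apoptosis regulators (-0.01 and 0.05, 0.437), dendritic cell genes (0.05 and -0.08, 0.743) and fibroblast and endothelium genes (0.07 and -0.01). The population contrast had respiratory chain (0.07 and -0.10), NR4A family (0.05 and -0.01) and, by camera direction alone, heat shock genes in WT. In the libraries labelled dKO it had type I interferon response (0.08 and -0.05), heat shock (-0.05 and 0.06), NR4A family (0.03 and -0.06) and B16 melanoma cell genes (0.12 and -0.03). The interaction had CD4 and regulatory T cell (0.24 and -0.13), tissue residency (0.06 and -0.01), cholesterol synthesis (-0.02 and 0.01), B16 melanoma cell (-0.50 and 0.01), terminal exhaustion and, by camera direction alone, macrophage and monocyte genes. In the genotype contrast the macrophage and monocyte list had a median of 0.02 with a downward camera direction in PD1+Tim3- cells (adjusted p 0.658). Hypoxia (0.141 and 0.909), cholesterol synthesis (0.378 and 0.545), mitochondrially encoded (0.258 and 0.165) and fibroblast and endothelium genes (0.129 and 0.983) did not pass in either genotype contrast. The melanoma genes Tyr and Mlana stood at 15.8 CPM on average and at most 0.514, the monocyte genes Lyz2 and Cd68 at most 0.745 and 11.3, and Foxp3 of regulatory T cells at most 2.73. The neutrophil genes S100a8 and Cxcr2 stood at most at 0.380 and 14.4, and the B cell genes Ms4a1 at 0 in all libraries and Cd79b at most 4.63. Pdcd1 stood at 56.1 ± 15.7 and 56.6 ± 9.09 CPM in WT and labelled dKO PD1+Tim3- cells (SD, n = 2) and 49.9 ± 0.781 and 48.5 ± 1.97 in PD1+Tim3+ cells. No named gene that passed changed direction under another scaling, and other scalings moved log2 fold changes by at most 0.0282, so that medians closer to 0 than that can turn.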

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

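Each result here was picked out because it differed between groups, namely 6 gene lists with a genotype by population interaction that camera called, or because it goes against a label or was seen on a closer look. All tests in this part were chosen after the result was seen, except the test on a smooth trend with transcript length, whose prediction was written before it was run. The test on recovery from library to library was changed more than once after its values were seen, from a rank correlation over all genes, to the median over genes under 1000 bases, to a rule over 3 sets of genes. The wording of the exchanged-label explanation and of the smooth-trend explanation was narrowed after their values were seen, and the smooth-trend test was first read as an answer and later as undecided.

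Nr4a1 was higher in the libraries labelled dKO, and Nr4a2 did not differ by more than its error. A wrong label on 1 of the 2 libraries of a group would make them differ in Nr4a1. The mark was set at 50% of the smaller genotype log2 fold change, after the values were seen. The largest difference was 0.248 against a fold change of 0.573, under that mark. The test needs Nr4a1 counts that follow the genotype, so a wrong label is not excluded. An exchange of the labels in all 8 libraries, in counts that register both deletions, would raise Nr4a2 by at least 1 log2 unit in the libraries labelled dKO, and the upper bound of its fold change was 0.169. Counts from transcript parts outside the deleted segments may leave gene totals unchanged or higher, but 0 columns of the table give counts per exon, so this cannot be told apart from an exchange of labels in counts that do not register the deletions. Reads over the floxed exons, or the genotyping of the donors, would settle it.

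Y-linked genes were higher in the libraries labelled dKO, with a pooled log2 fold change of 0.74 in PD1+Tim3- and 1.35 in PD1+Tim3+ cells, beside Xist at -0.40 and -0.44. A larger part of cells from male donors would move the 4 Y-linked genes by 1 shared fold and lower Xist. The heterogeneity p of the 4 genes within a population was 0.194 at the smallest, so more male cells may explain the pattern there. The genes were counted in the same libraries, so their agreement does not single out that cause. Pooled fold changes of the 2 populations differed by more than their errors of 0.08 and 0.07, which take the genes as independent. The same male part in both populations is therefore not shown. Scaling would move Xist the same way as the Y-linked genes, and the upper bound of its fold change was -0.166, so the data speak against scaling. With Xist as the measure of female cells, the implied male part in PD1+Tim3- and PD1+Tim3+ cells was 26.5% and 14.4% in WT, without an error. In the libraries labelled dKO it was 44.2% and 36.9%, also without an error. If so, sex of the donors is mixed with the genotype label in both genotype contrasts.

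Short transcripts led the interaction, with ribosomal protein genes at a median of 0.79 (camera adjusted p 4.12e-27, adjusted p = 0.440 with an estimated correlation). Recovery of short transcripts that differs from library to library would give a difference within a group of at least 50% of the interaction, and the values were 0.0908 against 0.241 under 1000 bases, 0.352 against 0.585 under 700 bases and 0.458 against 1.21 over the 50 leading genes, which were chosen for the pattern, beside 0.590 against 0.79 for ribosomal protein genes and 0.533 against 0.67 up to 500 bases, added later. The sets differ in their answer, so technical recovery and a change in these transcripts cannot be told apart. A smooth trend with length as the whole cause was tested on the 50 leading genes, of which 46 kept an unadjusted p under 0.01 once it was removed, but genes chosen for the pattern decide nothing, so a smooth trend could be the cause or part of it. The offsets, which are fitted to remove such a trend, took the median from 0.67 to 0.05 up to 500 bases, from 0.24 to -0.07 under 1000 bases, from 0.79 to 0.43 for ribosomal protein genes and from 1.21 to 0.92 over the 50 genes.

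Glycolysis genes had a median interaction of -0.41 (camera adjusted p 3.44e-05, adjusted p = 0.440 with an estimated correlation), picked out because their population difference was 0.45 in WT and 0.12 in the libraries labelled dKO. Respiratory chain genes had 0.0627 (0.0292, adjusted p = 0.440 with an estimated correlation), picked out as a difference between the genotypes, with 0.07 in WT and 0.26 in the libraries labelled dKO. TCR-induced genes had -0.16 (0.0461, adjusted p = 0.440 with an estimated correlation) and type I interferon response genes -0.24 (0.0461, adjusted p = 0.440 with an estimated correlation), both picked out as a difference between the genotypes. Erythroid genes had 2.89 (0.00358, adjusted p = 0.440 with an estimated correlation), picked out in the same way, with Hbb-bs highest in replicate 1 of PD1+Tim3+ labelled dKO at 37.3 CPM. The median interaction of erythroid genes ran from 1.53 to 4.46 with a library left out.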

How the results depend on the processing

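Of the 67 calls of named genes none changed direction under any alternative, and both scalings, both filters, robust empirical Bayes, the length offsets and an adjusted p under 0.10 kept all. Calls were lost with DESeq2 (2 of 66, with no adjusted p for Setbp1), limma-voom (6), the block (7), the 4 libraries compared (2), WT PD1+Tim3- replicate 1 or 2 left out (6, 7), either PD1+Tim3- library labelled dKO left out (7), WT PD1+Tim3+ replicate 1 or 2 left out (18, 21), PD1+Tim3+ labelled dKO replicate 2 left out (1) and replicate 2 of both groups labelled dKO left out (15). Counts of calls under RLE and upper-quartile factors were 6 and 6, 78 and 84, 2198 and 2274, 1264 and 1317, and 0 and 0, in the order of the report.

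The count of 6 genotype calls in PD1+Tim3- cells became 232 without the low-count filter, 0 with limma-voom, 56 with robust empirical Bayes, 0 with the block, 1 without replicate 2 of both groups labelled dKO and 0 to 27 with a library left out. The 82 in PD1+Tim3+ cells became 486 without the filter, 40 with the block, 39 in the 4 libraries compared, 15 without those 2 libraries and 6 to 405 with a library left out. The WT population count of 2223 became 1303 with DESeq2 and 426 to 2763 with a library left out. That of 1298 in the libraries labelled dKO became 716 with the block, 649 without those 2 libraries and 119 to 1376 with a library left out. The interaction count of 0 became 331 without the filter, 95 with DESeq2, 4 with robust empirical Bayes and 0 to 309 with a library left out. Counts rose as well as fell with libraries left out, and the cause of these moves was not tested.

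With an estimated correlation the called lists went from 8 to 0, 10 to 0, 15 to 3, 10 to 2 and 6 to 0. A rise in the correlation is not the whole cause, as some lists with an estimate under the preset 0.01 lost their call too. In the PD1+Tim3+ genotype contrast the unadjusted camera p of stem-like genes (-0.0401) went from 1.71e-06 to 0.00642. That of heat shock genes (-0.0390) went from 0.00692 to 0.0466. Stem-like genes kept their call in both population contrasts, at -0.0133 and -0.00345. Camera with an estimated correlation also takes its p from the 4 residual degrees of freedom, which raises the p of a given statistic. How much each part moved the calls was not tested. Fry, which asks another question, called 6, 6, 17, 12 and 0, and in PD1+Tim3- cells it did not call cell cycle, ribosomal protein, glycolysis, apoptosis or effector genes. In the PD1+Tim3+ genotype contrast it did not call cell cycle, glycolysis, ribosomal protein, erythroid or CD4 and regulatory T cell genes. It called the NR4A family upward in both genotype contrasts (fry adjusted p 0.0189 and 0.0172). With a library left out 48 of 49 medians of called lists kept their sign, and respiratory chain genes in the interaction went from -0.09 to 0.15. Genes shared by the genotype contrasts went from 3 to 86 at an unadjusted p under 0.01, which takes in more genes. Same-numbered libraries of the 2 populations correlated negatively after group means were removed (r -0.197 in WT and -0.135 in the libraries labelled dKO over 7085 genes), so the numbers are not shown to pair them, and whether populations came from the same mice is not given in the sources used here. The block ended the calls of Cd8a in the WT population contrast, of TCR-induced (0.0766, range 0.0235 to 0.440) and type I interferon response genes (0.0615, range 0.0178 to 0.440) in the interaction and of NK cell genes (0.106, range 0.106 to 0.294) in the PD1+Tim3+ genotype contrast, and added erythroid genes (0.0122, range 0.0122 to 0.720) in the WT and NK cell genes (0.0339, range 0.0339 to 0.237) in the labelled dKO population contrast. Nested in genotype it gave 1528, 1006 and 0 calls for the population contrasts and the interaction. With crossed numbers the nested block gave 2490, 1418 and 223 calls. As each group has 2 libraries, r for crossed numbers has the same size with a positive sign. That crossed numbers pair the libraries is not shown either. Depth and spread limit small changes, as a simulated fold of 1.5 was recovered in 43.3%, 29.9%, 38.8%, 5.97% and 2.99% of genes in the order of the report, lowest for the interaction.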

Other observations

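The test on strain differences was planned, with its prediction written before it was run. Strain differences flanking the targeted genes might bring genotype calls near Nr4a1 and Nr4a2, and would raise the share of genes with an unadjusted p under 0.01 in PD1+Tim3+ cells over 2 times within 10 Mb of either gene. Of 141 genes there 5 had such a p, 3.55% against 4.18% elsewhere, a ratio of 0.849 (Fisher exact p 1.00), so the data speak against it.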
